A study of Caenorhabditis elegans with 6 samples.

How the data were processed

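Polyadenylated RNA was measured in whole Caenorhabditis elegans collected at the L4 larval stage, in 3 WT and 3 TGQ samples. Per the labels, animals of both groups were grown from hatching at 20 °C on OP50 bacteria, and paired 150-base reads were sequenced from TruSeq libraries on an Illumina HiSeq instrument. The WT samples carry the strain name SJ4100 in the labels, the name of a strain with a GFP reporter driven by the hsp-6 promoter. Samples were assigned to groups and replicate numbers by their titles. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

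TopHat2 and RSEM are named, without versions or roles, per the submitters' processing notes. The genome build, the gene annotation and the tool of the differential test are not given in the sources used here. A single table of 5792 genes was analysed. It holds, for each gene, a deposited expression signal per sample with 2 decimals, whose unit is not named per the file headers. The signal is not a read count. In the authors' p-values, the implied squared error of low genes fell with a slope of -0.86 ± 0.01 (bootstrap SE) on log value and -0.87 ± 0.03 on log transcript length over 1049 genes, the behaviour of a value divided by length such as TPM or FPKM. The authors also deposited the mean signal of each group, the ratio of TGQ to WT as a fold change, its log2, and a p-value with its adjusted p-value.

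The largest adjusted p-value in the authors' deposited table was 0.0499, so the table holds genes selected on these same samples. The adjusted p-values in the authors' deposited table match a Benjamini-Hochberg adjustment over 16747 tests, of which the 5792 listed genes are 34.6%. Genes outside the table are not analysed here. The deposited log2 fold changes lay 0.131 below the log2 ratio of the group means (median difference of -0.131 over 3716 genes with both means of at least 5), so the authors scaled the samples differently for their test. Changes given here are from the signal values unless the authors' deposited table is named. The sign of the authors' fold differed from that of the mean ratio for 3 genes. No depth could be recovered: a search for a per-read step in the low values was matched or exceeded by 1 to 28 of 50 sets of randomly altered gene lengths per sample. The depth is therefore unknown, and no counting interval is given.

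The design fixed before the data were examined foresaw a count model for counts and limma for normalized values. The table holds no counts, so limma 3.58.1 in R 4.3.3 was fitted to log2(value + 1) of the genes with a value of at least 1 in at least 3 samples, with group as the single term and eBayes with trend and robust options. Fold changes are on this log2(value + 1) scale and understate the change of low genes. Adjusted p-values are Benjamini-Hochberg values over the 5540 genes tested, and a gene was called at an adjusted p under 0.05. Because the authors had already selected the genes, these calls are not independent evidence across the genome. All 42 gene lists were fixed before the data were examined. Camera, with a preset correlation of 0.01 between genes, compared each of the 37 lists having at least 5 tested members with the other genes of the table, never with unlisted genes. Calls per list were also counted with p adjusted over the list alone. After the data were seen, a one-sided hypergeometric test was added for over-representation of each list in the table. It counted every annotated protein-coding member as tested, over 16747 genes, which understates enrichment wherever such a member was not tested. Members of other gene types, such as the pseudogenes fbxa-191 and fbxa-193, were counted only where they were in the table. In families with such members this overstates enrichment and the share of members in the table. It also took genes as independent. Where genes of a list move together or share reads, its p-values are too small and overstate the evidence.

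On simulated data with 5540 genes of the means and spreads of this comparison, 200 of them changed, 77% of genes changed by 1 on the log2 scale and 25.4% of those changed by 0.5 were recovered over 5 runs, and 4.7% of calls were false. Far more genes were called in the real fit, 4998 of 5540. The p needed for a call was therefore smaller in the simulation, and its rates of recovery and false calls do not describe the real fit. A list shifted by 0.5 was called in 20 of 20 runs, and other lists in 2 of 720 tests. The simulated genes were independent of each other, unlike those measured, whose estimated correlation within lists ran from 0 to 0.99. In the real samples camera called 14 to 23 of 37 lists when the groups were mixed, and what gave those calls was not tested. The simulated rate of false list calls was therefore not shown to carry over. Sums over a list were compared by an exact two-sided permutation test in SciPy 1.17.1, whose smallest p with 3 against 3 samples is 0.1. The 28 somatic markers with which lists were compared, a choice made after the data were seen, are the tested members of the neuron, muscle, intestine and hypodermis lists that belong to neither the moulting nor the collagen list.

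Genes named in the text follow a rule fixed before the data were examined. They are the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 and no overlap between the groups, hsp-6, hsp-60, atfs-1, dve-1, ubl-5, egl-20 and the 12 mRNAs of the mitochondrial genome, up to 4 called members with the lowest adjusted p per list described, and the 3 genes of highest mean. Of these, dve-1, ubl-5 and the mitochondrial mRNA ndfl-4 are not analysed here. Identifiers of 5789 genes matched the Ensembl release 115 annotation of WBcel235, from which coordinates and gene types are given. 22 genes have values identical in all 6 samples to those of another gene, and values within families of near-identical genes, such as collagens, major sperm proteins and histones, are uncertain because reads can be shared. Alternatives tried were other filters, a pseudocount of 0.1, quantile normalization, the replicate number as a block, leaving out each sample, a test against a 1.5-fold change, other list tests and, added after seeing the data, the authors' scaling.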

Results

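The series asks how gene expression differs between WT animals and TGQ animals, in a project whose title concerns inherited elevation of mitochondrial DNA (mtDNA), the mitochondrial unfolded protein response (mitochondrial UPR) and aging. The mitochondrial UPR is a nuclear transcriptional response that raises mitochondrial chaperones and proteases under mitochondrial stress. The labels give TGQ as a strain name. What it stands for, how these animals were derived, and whether they carry the hsp-6 reporter known for the WT strain, SJ4100, are not given in the sources used here. RNA of whole L4 animals, the last larval stage, was measured in 3 WT and 3 TGQ samples. The values of the 5792 genes summed to between 327792 and 349508 per WT sample and between 282762 and 293887 per TGQ sample. In log2(value + 1), correlations between samples were 0.987 to 0.995 within WT, 0.989 to 0.993 within TGQ and 0.87 to 0.919 between the groups. The groups separated on the main principal component, with 88% of the variance. The authors had selected the genes for a difference between these groups, so a separation of the groups was expected and its size does not describe the whole transcriptome. On the next component, with 6.6% of the variance, WT replicate 1 lay at 15.6, and the other samples lay between -12.8 and 7.1.

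In the authors' deposited table, 2692 genes (46.5%) were higher and 3100 genes (53.5%) lower in TGQ. Of these, 588 were at least 2-fold higher and 1281 at least 2-fold lower by the authors' deposited table. Genes higher in TGQ included genes of the mtDNA, mitochondrial chaperones, detoxification enzymes and moulting factors, while genes lower in TGQ included yolk protein, oocyte, sperm and many collagen genes. With limma on the values, 4998 of 5540 genes tested were called, 2527 higher (50.6%) and 2471 lower (49.4%). This even split depends on the scaling. The authors' scaling gave 2229 higher (43.5%) and 2891 lower, and quantile normalization 2555 higher (52.5%) and 2308 lower. At least 2-fold changes were called for 1090 genes, 364 higher and 726 lower. The split was 251 higher and 916 lower with the authors' scaling, 474 and 632 after quantile normalization, and 611 and 913 with a pseudocount of 0.1. The 2 groups did not overlap for 91.2% of the genes tested, against 10% by chance. The table holds genes that had passed the authors' test on the same samples, so these shares describe the selected genes. The median log2 change of the genes tested was -0.22, and it was -0.35 with the authors' scaling and -0.1 after quantile normalization.

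The 10 largest rises were those of F25E5.7, col-41, W09B7.1, F07B7.1, col-54, C29F3.3, ZK970.7, fbn-1, dpy-17 and grd-13. The value of F25E5.7 was 1.04 ± 0.949 (SD, n = 3) in WT and 44.7 ± 6.86 in TGQ, a log2 change of 4.57 (SE 0.27, adjusted p = 3.94e-06, limma). The collagen gene col-41 went from 13.1 ± 1.26 to 227 ± 55.8, a log2 change of 3.98 (SE 0.18). The collagen gene dpy-17, needed for body shape, rose 5.88-fold, and grd-13, a gene of the hedgehog-related family, rose 5.69-fold. The 10 largest falls were those of pud-3, col-101, F59C6.18, col-127, col-126, col-137, col-143, col-8, col-119 and Y22D7AR.10, of which 7 were collagen genes. The value of pud-3 was 30.5 ± 9.11 in WT and 0.55 ± 0.01 in TGQ. The adjacent collagen genes col-126 and col-127, on chromosome IV at 11263401 to 11264397 and 11264908 to 11266190 (WBcel235; the authors' build is not given in the sources used here), had log2 changes of -3.61 and -3.63, and reads may be shared between them. Among the 3 genes of highest mean, dct-16 stood at 6367 ± 62.9 in WT and 5831 ± 276 in TGQ (adjusted p = 0.0776), and it was called lower with the authors' scaling (adjusted p = 0.00461) and without TGQ replicate 1 (adjusted p = 0.0332). The fatty acid and retinol binding protein gene far-2 stood at 6182 ± 196 and 4850 ± 146, a fall called by limma. After quantile normalization its change was 0. That method gives a gene of the same rank in every sample the same value, so this loss says nothing against the fall. The collagen gene col-3 rose from 2574 ± 230 to 4143 ± 618.

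mRNAs encoded by the mtDNA were higher in TGQ. These mRNAs encode core subunits of the respiratory chain and the ATP synthase. Of the 12 such mRNAs, 11 were analysed and all 11 were called higher, also when adjusted over the list alone, with log2 changes from 0.81 to 1.85 and a median of 1.17. Their summed value was 5419 ± 379 (SD, n = 3) in WT and 11409 ± 955 in TGQ, 2.11 times as high, and every TGQ sample lay above every WT sample (exact two-sided permutation p = 0.1, the smallest that 3 against 3 samples allow). As a share of the summed values of the listed genes, they made up 1.62% ± 0.05 in WT and 3.97% ± 0.26 in TGQ. That total covers only genes selected for change and was lower in every TGQ sample than in every WT sample, which adds to the rise of the share. The cytochrome b mRNA ctb-1, at 4504 to 5621 of the mitochondrial chromosome in WBcel235, went from 1142 ± 3.31 to 2343 ± 82.1, a log2 change of 1.03 (SE 0.07, adjusted p = 5.01e-06, limma). The ATP synthase subunit mRNA atp-6, at 2634 to 3235, rose 3.6-fold from 131 ± 14.3 to 475 ± 72.8. The complex I subunit mRNA nduo-6, at 113 to 549, rose 3.33-fold, nduo-2 2.92-fold, nduo-3 2.65-fold and nduo-5 2.25-fold. The cytochrome oxidase subunit mRNAs ctc-1, ctc-2 and ctc-3 rose 2.35-fold, 2.09-fold and 2-fold, and the smallest rises were those of nduo-4 (1.88-fold) and nduo-1 (1.75-fold). The ends of nduo-1 and atp-6, and of nduo-3 and nduo-5, overlap in the annotation, where reads could be given to either gene. Both mitochondrial ribosomal RNAs, named here after their values were seen, were also higher, MTCE.7 with 19.02 ± 3.43 in WT and 36.8 ± 3.43 in TGQ, and MTCE.33 with 8.84 ± 1.36 and 24.1 ± 3.58. Polyadenylated RNA was measured, so these values may not follow the amount of ribosomal RNA. The list was called higher than the other genes of the table (camera adjusted p = 1.2e-05), with an adjusted p = 0.46 with an estimated correlation, and was over-represented in the table (hypergeometric adjusted p = 0.00054). The same TGQ samples had lower oocyte, sperm and yolk protein mRNAs, with a summed oocyte and eggshell value of 500 ± 96 against 1893 ± 324 in WT, and 26 of 28 listed markers of neurons, muscle, intestine and hypodermis had higher values, with a mean log2 change of 0.63 against 1.25 for the mtDNA mRNAs (difference 0.62, two-sided permutation p = 2e-05, the smallest that the resampling can give, over 11 and 28 genes, which are not independent replicates).

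Genes of mitochondrial chaperones, proteases and protein import rose together. Of 16 list members, 12 were analysed and all 12 were called higher, also when adjusted over the list alone, with log2 changes from 0.42 to 0.96 and a median of 0.51. The mitochondrial HSP70 gene hsp-6, on chromosome V at 4824124 to 4826760, was at 237 ± 33.5 (SD, n = 3) in WT and 343 ± 10.2 in TGQ, a 1.45-fold rise (log2 0.54, SE 0.11, adjusted p = 0.00171, limma). The log2 change of hsp-6 in the authors' deposited table was 0.41. The mitochondrial chaperonin gene hsp-60 went from 311 ± 39 to 430 ± 14.4, a 1.39-fold rise (adjusted p = 0.00246). The mitochondrial DnaJ gene dnj-10 rose 1.58-fold, the prohibitin genes phb-1 and phb-2 rose 1.4-fold and 1.43-fold, and tomm-20, a subunit of the outer membrane import complex, rose 1.42-fold. The list was called higher by camera (adjusted p = 0.002), with an adjusted p = 0.46 with an estimated correlation, and was over-represented in the table (adjusted p = 0.0069). Its mean log2 change of 0.56 lay 0.08 below that of the 28 listed somatic markers (difference of -0.08, two-sided permutation p = 0.53 over 12 and 28 genes), so the rise was not shown to exceed that of these markers. They are only markers that had passed the authors' test. Of the annotated members, 25% of the neuron, 37.5% of the muscle, 47.6% of the intestine and 35.3% of the hypodermis list were in the table, against 75% of this list. The comparison therefore does not cover somatic transcripts outside the table. The rise of the chaperone list went with the lower summed oocyte and eggshell value of TGQ (500 ± 96 against 1893 ± 324 in WT).

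Of 15 regulators of the mitochondrial UPR and its chromatin factors, 5 were tested and all 5 were called higher, or 4 with the authors' scaling, but the list itself did not pass (camera adjusted p = 0.056). It passed after quantile normalization (0.042) and without WT replicate 1 (0.041). The transcription factor gene atfs-1, which drives the response, went from 31.5 ± 4.75 to 41.4 ± 0.858 (log2 0.39, SE 0.13, adjusted p = 0.0162). This call was lost without TGQ replicate 2 (adjusted p = 0.056) and with the authors' scaling (adjusted p = 0.072). The histone demethylase gene jmjd-3.1 rose 2.03-fold and the lysosomal transcription factor gene hlh-30 rose 1.39-fold. The Wnt ligand gene egl-20 went from 2.94 ± 0.553 to 5.23 ± 1.15 (log2 0.65, SE 0.18, adjusted p = 0.00704). Among 9 Wnt pathway genes tested, 7 were called higher, including the ligand gene cwn-2 with 1.87-fold, and 1 lower, the ligand gene mom-2, which fell by 0.97 on the log2 scale (camera adjusted p = 0.098).

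**Figure D1:**
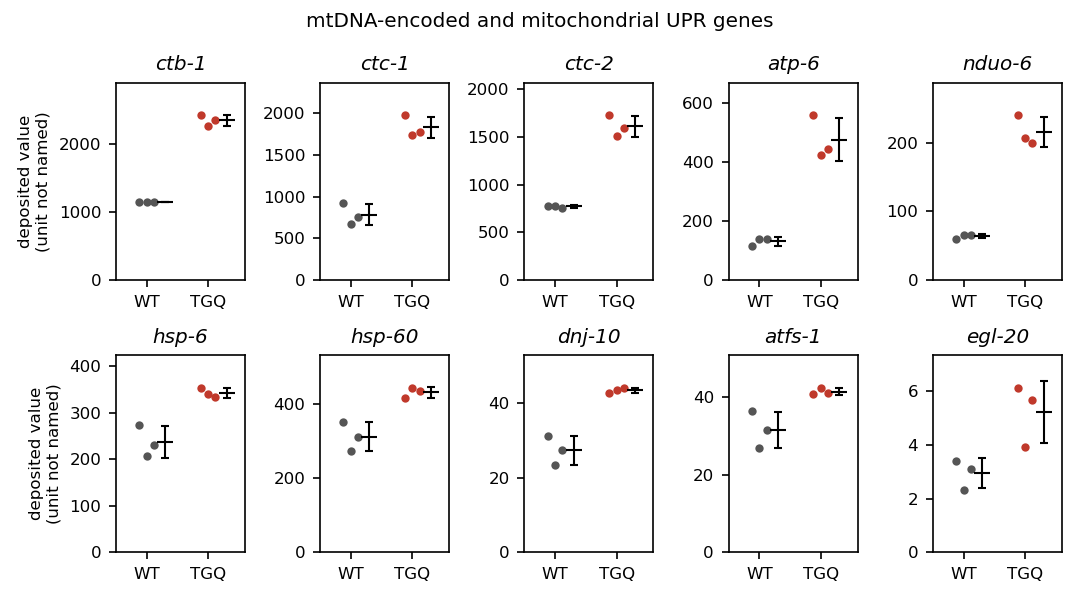
Deposited expression values (y axes from 0, unit not named in the table) of 5 mtDNA-encoded genes and 5 nuclear genes in the 3 WT (grey) and 3 TGQ (red) samples; dashes with bars are means ± SD. The TGQ samples lay above the WT samples for all 10 genes, with ctb-1 at 1142 ± 3.31 in WT and 2343 ± 82.1 in TGQ.

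Nuclear genes of respiratory complex I, mitochondrial ribosomes and central metabolism were mostly higher among those in the table. All 6 tested genes of respiratory complex I were called higher (median log2 change 0.45, or 0.72 after quantile normalization, camera adjusted p = 0.028), among them gas-1 with 1.54-fold and nuo-1 with 1.32-fold. Of the 22 mitochondrial ribosomal protein genes tested, 21 were called higher and 0 lower, or 20 and 1 with the authors' scaling (median 0.47, camera adjusted p = 0.00046), among them mrps-30 with 1.63-fold and mrpl-11 with 1.34-fold. Of the 14 genes of the tricarboxylic acid cycle list, which also holds genes of cytosolic enzymes, 13 were called higher, or 12 with the authors' scaling (median 0.47, camera adjusted p = 0.00096), including the cytosolic isocitrate dehydrogenase gene idh-1 with 1.67-fold, the cytosolic aconitase gene aco-1 with 1.85-fold, and pck-2, which encodes the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, with 1.71-fold. All 7 listed genes of one-carbon, glutathione and hypoxia metabolism were called higher, or 6 with the authors' scaling (median 0.64, camera adjusted p = 0.0081), with cysl-2 at 1.83-fold and the cystathionine beta-synthase gene cbs-1 at 1.88-fold. Each of these 4 lists had an adjusted p = 0.46 with an estimated correlation. Only 30%, 31.4%, 58.3% and 38.9% of their annotated members were in the table, and none of the 4 was over-represented there (adjusted p of 1, 1, 0.051 and 0.96). In these samples oocyte and eggshell genes had a median log2 change of -1.58 and the somatic markers a mean of 0.63.

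Other complexes went both ways. Of 6 tested genes of complexes II to V, 3 were called higher, including sdha-1 with 1.52-fold and cyc-1 with 1.35-fold, and 2 lower, including ucr-2.3, which fell by 0.39 on the log2 scale (camera adjusted p = 0.57). The lower calls numbered 3 with the authors' scaling and 1 after quantile normalization. Of the mtDNA maintenance, expression and dynamics list, 4 of 13 genes were tested. The fission GTPase gene drp-1 was called higher (1.49-fold, adjusted p = 0.00901), as were the mitochondrial RNA polymerase gene rpom-1 (adjusted p = 0.0203) and the fusion gene eat-3 (adjusted p = 0.0254), and hmg-5, whose product binds mtDNA, was called lower (adjusted p = 0.0275). The calls of rpom-1, eat-3 and hmg-5 were each lost when single samples were left out, and those of rpom-1 and eat-3 also with the authors' scaling. Without WT replicate 2 the log2 change of eat-3 was 0.37 in place of 0.59. Cytosolic ribosomal protein genes were nearly absent from the table, with 4 of 81, of which 1 was called higher, rpl-11.2, and 3 lower, including its paralog rpl-11.1. Of 11 glycolysis genes, 8 were called higher and 3 lower (camera adjusted p = 0.13). The glyceraldehyde-3-phosphate dehydrogenase paralogs moved in opposite directions, gpd-2 and gpd-3 rising 1.58-fold and 1.41-fold, and gpd-1 and gpd-4 falling with log2 changes of -1.32 and -0.9.

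Cuticle collagen genes changed widely and in both directions. Of 113 tested, 80 were called lower and 29 higher (median log2 change -0.74, camera adjusted p = 2.8e-05, and adjusted p = 0.46 with an estimated correlation). After quantile normalization the median was -0.42, with 67 called lower and 29 higher. Of the annotated collagen genes, 64.6% were in the table (hypergeometric adjusted p = 9.9e-15). Their summed value was 70802 ± 1530 (SD, n = 3) in WT and 46989 ± 1065 in TGQ. The adult collagen gene col-19 fell from 772 ± 111 to 97.5 ± 31, by 3.01 on the log2 scale (SE 0.2, adjusted p = 5.41e-06, limma). Factors of the moulting cycle went the other way, with 19 of 20 called higher and 1 lower (median 1.09, camera adjusted p = 5.1e-06, and adjusted p = 0.46 with an estimated correlation). These 20 genes were 71.4% of the list (hypergeometric adjusted p = 0.00054). The fibrillin-like gene fbn-1 rose from 2.5 ± 0.407 to 21.5 ± 2.83, the apical matrix gene noah-1 rose 3.5-fold, and the moulting protease inhibitor gene mlt-11 rose 3.68-fold. In the heterochronic list, which holds regulators of larval timing, 6 of 7 genes were called higher, including lin-29 with 1.87-fold, its cofactor gene mab-10 with 2.15-fold and hbl-1 with 2.02-fold, while the adult marker col-19 was the fall (camera adjusted p = 0.079). The value of hbl-1 was low, 1.02 ± 0.25 in WT and 3.06 ± 0.299 in TGQ, so the added 1 understates its fold.

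**Figure D2:**
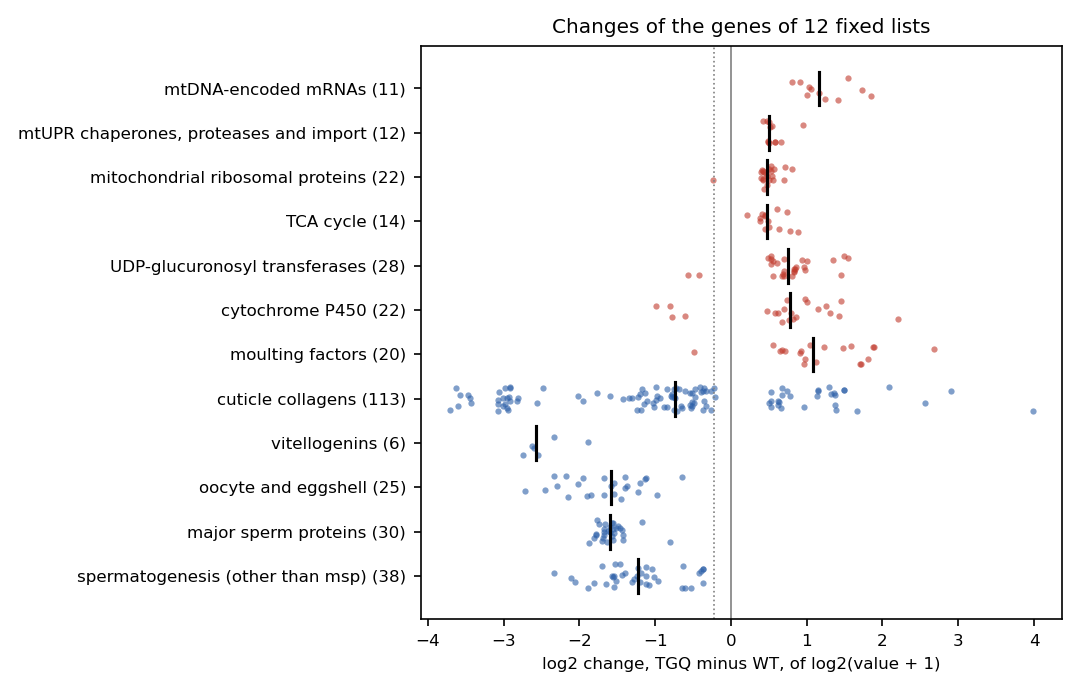
Each point is the log2 change (TGQ minus WT, of value + 1, x axis) of 1 tested gene in 12 of the fixed lists, with the number of genes in brackets and a black line at each list's median; red and blue mark lists with a median above and below 0. The dotted line marks the median of the genes tested, -0.22, and the medians run from -2.58 for vitellogenins to 1.17 for mtDNA-encoded mRNAs.

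Oocyte and sperm transcripts were lower in TGQ. All 25 tested oocyte and eggshell genes were called lower (median log2 change -1.58, camera adjusted p = 8.1e-08), as were all 30 major sperm protein genes (median -1.6, adjusted p = 1.2e-11) and all 38 other spermatogenesis genes, or 37 after quantile normalization (median -1.23, adjusted p = 2.3e-09). Each list had an adjusted p = 0.46 with an estimated correlation, and each was over-represented in the table (hypergeometric adjusted p of 7e-10, 4.7e-10 and 4e-06). The eggshell genes perm-2 and perm-4 fell from 331 ± 45.2 to 51.2 ± 18.8 and from 270 ± 27.7 to 49.7 ± 15.5 (SD, n = 3). The sperm-binding oocyte gene egg-1 and the eggshell proteoglycan gene cpg-1 had log2 changes of -2.02 and -2.34. The major sperm protein gene msp-142 fell from 315 ± 28.4 to 90.8 ± 5.47 and msp-33 from 432 ± 31.9 to 141.6 ± 9.61, and the sperm-specific genes nspd-7 and nspd-2 had log2 changes of -1.55 and -1.53. The summed major sperm protein value was 12410 ± 1311 in WT and 4047 ± 431 in TGQ.

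Of 13 genes of mitotic and meiotic germ cells, 7 were called lower and 1 higher, and 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.098). With the authors' scaling 11 were called lower and 1 higher, and the median of -0.34 was -0.22 after quantile normalization. The meiotic regulator gene gld-1 fell by 1 on the log2 scale, and mes-3 rose 1.46-fold. Of 13 histone genes, 11 were called lower, including his-38, and 1 higher, the linker histone gene his-24 (median -0.7, camera adjusted p = 0.015, adjusted p = 0.46 with an estimated correlation, and 0.075 among genes with a mean of at least 5). Of 11 genes of small RNA inheritance and chromatin, 4 were called higher, including the nuclear Argonaute gene nrde-3 with 1.7-fold, and 4 lower, including the germ line Argonaute gene wago-4, which fell by 0.8 on the log2 scale. The median of this list was -0.21, its mean 0.01 and its camera direction up (adjusted p = 0.89), and the median was -0.34 with the authors' scaling and -0.08 after quantile normalization. The list of male tail and male-enriched genes had 3 of 19 members in the table, all called higher, namely dmd-3 with 2.77-fold, mab-3 with 2.33-fold and fog-3 with 1.97-fold. The value of dmd-3 was low, 0.307 ± 0.138 in WT and 2.67 ± 0.773 in TGQ, so the added 1 understates its fold. Its log2 change in the authors' deposited table was 2.93. The product of fog-3 is required for germ cells to enter spermatogenesis in hermaphrodites as well as in males.

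Genes of the 6 vitellogenins, the yolk proteins made in the intestine, were all called lower (median log2 change -2.58, camera adjusted p = 0.0053, and adjusted p = 0.46 with an estimated correlation). Their summed value was 2537 ± 946 (SD, n = 3) in WT, where replicate 1 had 3617 and the other replicates 1852 and 2142, and 440 ± 169 in TGQ. The value of vit-6 was 879 ± 327 in WT and 149 ± 55.0 in TGQ, and vit-2, vit-4 and vit-1 had log2 changes of -2.6, -2.75 and -1.88. Among 10 tested intestine markers, 8 were called higher, including the cysteine protease gene cpr-5 with 1.84-fold and the acid phosphatase gene pho-1 with 1.76-fold, and 2 lower, including cpr-1, whose call was lost after quantile normalization (camera adjusted p = 0.089). With the authors' scaling 5 were called higher and 2 lower, and after quantile normalization 8 higher and 0 lower, with the list itself called (adjusted p = 0.027). Of 9 genes of lipid synthesis and desaturation, 7 were called higher and 2 lower (adjusted p = 0.12). The delta-9 desaturase genes fat-5 and fat-7 had log2 changes of -1.48 and -0.96, while the delta-6 desaturase gene fat-3 rose 1.76-fold and the methionine adenosyltransferase gene sams-1 rose 1.73-fold. Of 15 genes of lipolysis and fatty acid oxidation, 10 were called higher and 5 lower (camera adjusted p = 0.12, and 0.015 among genes with a mean of at least 5), and the list was over-represented in the table (adjusted p = 0.038). The acyl-CoA dehydrogenase gene acdh-2 rose 3.18-fold and the enoyl-CoA hydratase gene ech-6 1.65-fold, and the lipase gene lipl-5 fell by 0.69 on the log2 scale.

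**Figure D3:**
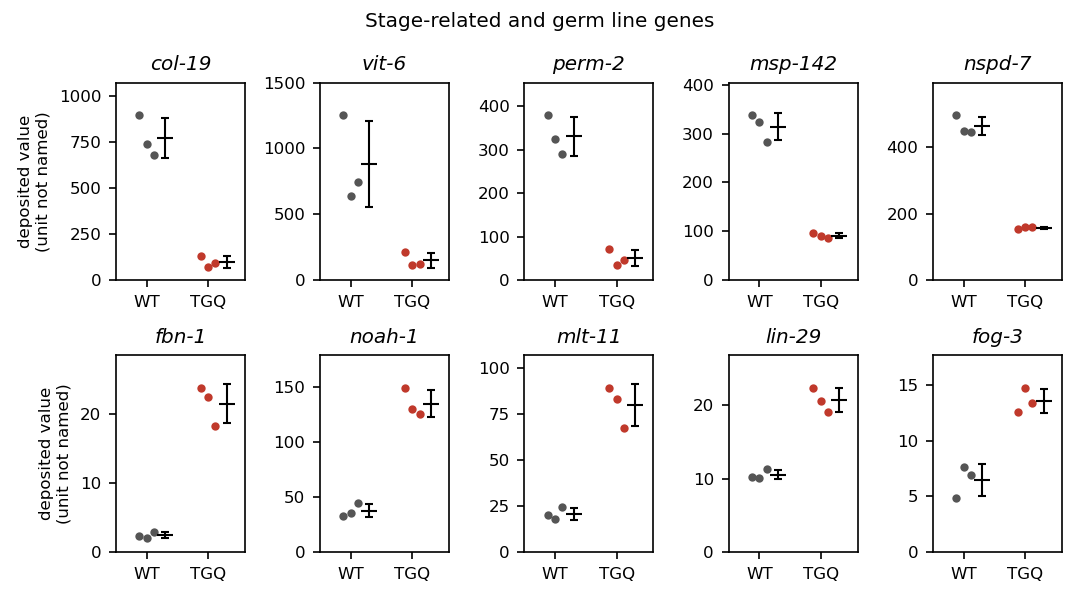
Deposited expression values (y axes from 0, unit not named in the table) of 10 genes of cuticle, yolk, oocyte, sperm, moulting and germ cell fate lists in the 3 WT (grey) and 3 TGQ (red) samples; dashes with bars are means ± SD. The groups did not overlap for these genes, with col-19 at 772 ± 111 in WT and 97.5 ± 31 in TGQ.

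Markers of somatic tissues were higher among the listed genes. All 6 tested neuronal genes were called higher (median log2 change 0.65, camera adjusted p = 0.027), including the GABA synthesis gene unc-25 with 1.58-fold and the synaptotagmin gene snt-1 with 1.68-fold. All 9 muscle genes were called higher, or 7 with the authors' scaling (median 0.66, adjusted p = 0.0088), including the troponin I gene tni-1 with 1.7-fold and the myosin gene myo-1 with 1.7-fold. All 6 hypodermis and seam cell genes were called higher (median 1.16, adjusted p = 0.0081), including the larval collagen gene dpy-7 with 2.6-fold, tbx-2 with 1.72-fold and grd-10 with 3.24-fold, and grd-10 is also a member of the moulting list. Each of these 3 lists had an adjusted p = 0.46 with an estimated correlation, and 25%, 37.5% and 35.3% of their members were in the table. Of 12 neuropeptide genes tested, 5 were called higher, including nlp-16, and 6 lower, including nlp-25, which fell by 2.41 on the log2 scale. The median of this list was -0.3 and changed sign to 0.03 after quantile normalization (camera adjusted p = 0.86).

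Detoxification enzymes and nuclear receptors were mostly higher among those in the table. Of 28 UDP-glucuronosyl transferase genes tested, 26 were called higher and 2 lower (median log2 change 0.76, camera adjusted p = 2.3e-05), including ugt-57 with 2.92-fold and ugt-16 with 2.74-fold, and the family was over-represented in the table (adjusted p = 0.039). Of 22 cytochrome P450 genes, 18 were called higher and 4 lower (median 0.78, camera adjusted p = 0.0017). Of these, cyp-13B1 rose from 4.62 ± 0.26 to 24.8 ± 1.24 (SD, n = 3) and cyp-14A5 rose 2.74-fold. Of 47 nuclear hormone receptor genes, 45 were called higher and 1 lower, and 45 higher and 2 lower adjusted over the list alone (median 0.6, camera adjusted p = 3.6e-07, with 42 higher and 2 lower under the authors' scaling), including nhr-91 with 2.49-fold and nhr-97 with 1.81-fold. Each of these 3 lists had an adjusted p = 0.46 with an estimated correlation. Only 18.9% of the annotated nuclear receptor genes were in the table, against 34.6% of all genes in the authors' test. The shares were 49.3% for the UDP-glucuronosyl transferases and 36% for the cytochrome P450 genes. Of 11 glutathione S-transferase genes, 7 were called higher, including gst-20 with 2-fold, and 1 lower (camera adjusted p = 0.13), or 6 higher and 4 lower with the authors' scaling. Of 53 F-box and MATH family genes, 29 were called higher, including fbxa-72 with 2.6-fold, and 15 lower (14 adjusted over the list alone), with a camera adjusted p = 0.13. With the authors' scaling 28 of them were called higher and 24 lower. Only 25% of the annotated glutathione S-transferase genes and 14.4% of the F-box and MATH family genes were in the table. The somatic markers of the same samples had a mean log2 change of 0.63.

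Other stress and immune lists showed mixed directions. C-type lectin genes were the exception that passed, with 32 of 46 called lower and 12 higher (median log2 change -0.58, camera adjusted p = 0.013, and adjusted p = 0.46 with an estimated correlation), a list call lost among genes with a mean of at least 5 (adjusted p = 0.05), and clec-91 and clec-229 had log2 changes of -2.38 and -1.77. Only 21.7% of the annotated C-type lectin genes were in the table. Of 9 other innate immune effector genes, 6 were called lower, including the lysozyme genes lys-4 and lys-7, and 1 higher, the antimicrobial peptide gene nlp-29 with 1.97-fold (adjusted p = 0.12). After quantile normalization 4 were called lower and 2 higher, and with the authors' scaling 8 lower and 1 higher. Of 11 genes of the endoplasmic reticulum UPR, 7 were called higher, including the chaperone genes hsp-3 with 1.48-fold and enpl-1 with 1.52-fold, and 3 lower, including abu-1 and abu-11, whose products are also linked to the pharyngeal cuticle (adjusted p = 0.22). Of the cytosolic heat shock list, 3 of 19 genes were tested and 2 were called lower, hsp-43 and hsb-1, and 1 when adjusted over the list alone. The call of hsb-1 (adjusted p = 0.0493) was lost under several alternatives, and the list had 3 lower calls with the authors' scaling and 1 lower and 1 higher after quantile normalization. Of 7 oxidative stress genes, 6 were called higher (5 with the authors' scaling), including dhs-8 and the catalase gene ctl-1, and 1 lower, ctl-3 (camera adjusted p = 0.1). Of 7 insulin and DAF-16 pathway genes, 3 were called higher, including asm-2, and 4 lower, including fat-7 (adjusted p = 0.82). Of 47 genes of the intracellular pathogen response, 3 were tested, of which pals-1 and cul-6 were called higher and pals-32 lower, and the pals-32 call was lost when single samples were left out.

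Over all lists, camera called 20 of 37, 13 higher and 7 lower than the other genes of the table. With an estimated correlation, camera called 0 lists, and 3 had an unadjusted p under 0.05, the smallest being 0.044. Fry, which asks whether the genes of a list move on balance in one direction and does not compare them with other genes, called 33, in a table whose genes had been selected for change. The counts of called members adjusted over the list alone were the same for 38 of the 42 lists. Against the count of annotated members, 11 lists were over-represented in the table, the heterochronic list (adjusted p = 0.04) and the vitellogenins (adjusted p = 0.009) among them.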

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

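The authors' scaling was chosen after seeing the data, and the other alternatives before. Over the filters, a pseudocount of 0.1, quantile normalization and the authors' scaling, 3730 to 5222 genes were called, and leaving out single samples gave 4445 to 4800. With at least 2-fold change, 834 genes were called at a mean value of at least 5, 1097 with no filter on low values and 1524 with a pseudocount of 0.1 (611 higher, 913 lower). The authors' scaling gave 1167 (251 and 916), quantile normalization 1106 (474 and 632) and leaving out single samples 1036 to 1202. Called lists numbered 19 at a mean value of at least 5, where C-type lectins (adjusted p = 0.05) and histones (0.075) were lost and lipolysis was gained (0.015). They numbered 22 after quantile normalization, with mitochondrial UPR regulators (0.042) and intestine (0.027) gained. Without single samples they numbered 20 to 21, and the mean log2 change ranged from 0.475 to 0.641 for mitochondrial chaperones and from 1.195 to 1.285 for mtDNA mRNAs. No sample left out turned the sign of a called gene, and quantile normalization turned 38 signs. A test against a 1.5-fold change called 1049 genes (365 higher, 684 lower), fewer by its construction. With an estimated correlation in camera, 0 lists were called in place of 20, and the mitochondrial chaperones (mean 0.558) and the mtDNA mRNAs (mean 1.25) each had an adjusted p = 0.46; the estimates were 0.36 and 0.37 in place of 0.01. Fry called 33 lists, 25 higher and 8 lower.

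Of 140 named genes, 1639 of 1669 values under 12 alternatives kept direction and call, 28 values of 8 genes lost the call, 2 values of dct-16 gained it and 0 turned direction; the cause was not tested. The replicate numbers were not shown to pair the samples, since same-numbered deviations correlated at 0.25, -0.01 and 0.16 and WT replicate 2 correlated best with TGQ replicate 3 (0.17). With the replicate block, 5137 genes, 1081 with at least 2-fold change and 20 lists were called, and the list means were 0.558 and 1.25. The planned count models and count normalizations were not run because the values are not counts. Depth is unknown, so low values cannot be weighed by their reads.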

Other observations

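The terms and the chromosome split given here, and the tests of explanations, were chosen after the results were seen; the counts over other splits of the samples were planned. By the functional terms in the table, 678 terms with at least 10 genes were tested for direction with Fisher's exact test against the other listed genes, by the sign of the change in the authors' deposited table. Of these, 358 had an adjusted p under 0.05, 300 mostly higher and 58 mostly lower, so the terms given here are a choice among many. Membrane excitability and transport genes were mostly higher in TGQ. Of 49 genes with ion channel activity, 47 were higher and 2 lower (adjusted p = 5.7e-12), and of 59 synapse genes 52 were higher (adjusted p = 7.2e-10). The potassium channel gene kvs-5 went from 7.78 ± 0.873 (SD, n = 3) to 16.03 ± 0.252, and the cation channel gene trpa-1 from 2.17 ± 0.486 to 4.72 ± 0.559. All 23 genes of the pathway term for ABC transporters were higher (adjusted p = 3.9e-07). Among them were haf-6 with 7.78 ± 3.17 in WT and 35.4 ± 4.12 in TGQ, and mrp-2 with a 1.94-fold rise. A broader transport ATPase term, which also holds haf-6 and mrp-2, had 27 genes higher and 5 lower, with wht-4 among the lower. Of 50 peroxisome genes 41 were higher (adjusted p = 6e-06), and of 36 genes of branched-chain amino acid degradation 31 were higher (adjusted p = 2e-05), including hach-1, which went from 447 ± 55.6 to 972 ± 13.6. In the same samples 26 of 28 somatic markers were higher, with a mean log2 change of 0.63, and all 25 oocyte and eggshell, 30 major sperm protein and 38 other spermatogenesis genes tested were called lower. These named genes were chosen after their values were seen, and genes sharing a term are not independent.

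Genes lower in TGQ lay in other terms. Of 60 listed genes annotated with the term protein tyrosine phosphatase activity, 54 were lower (adjusted p = 3.8e-08), including the egg activation genes egg-3 and egg-4, with log2 changes of -1.37 and -1.12. The term does not show that each product is an active enzyme. Of 52 cell division genes, 45 were lower (adjusted p = 1.1e-05), among them the eggshell gene cpg-1 with a log2 change of -2.34. The cyclin D gene cyd-1 of the same term rose 2.05-fold. Of 896 listed X-linked genes, 669 (74.7%) were higher, against 2007 of 4880 (41.1%) on the autosomes, where the share ran from 36.4% on chromosome IV to 48.5% on chromosome V.

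Higher mtDNA mRNAs in TGQ were weighed against 3 explanations. A scaling factor per sample, or a smaller germ line that raised all other transcripts alike, would leave these mRNAs level with the 28 listed somatic markers of the same samples. Their mean log2 change was 0.62 higher (95% interval over samples 0.35 to 0.88, permutation over genes p = 2e-05, the smallest the resampling can give, with genes that are not independent). With these markers, that argues against each as the whole cause. The markers were chosen after the data were seen and leave out moulting and collagen genes. The 6 tested hypodermis and seam cell genes, grd-10 of the moulting list included, had a mean of 1.2 against 1.25 for the mtDNA mRNAs. Some somatic genes thus rose about as far, and the difference depends on the markers chosen. The mtDNA mRNAs and the markers come from a table of genes that had changed, and the effect of that selection on the difference was not tested. An earlier point of L4 in TGQ cannot be told apart from the group, because stage genes and group move together and 3 samples within a group allow no permutation p below 0.33. A higher mtDNA content, the subject of the study, stays open as well and was not measured by these values.

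Higher mitochondrial UPR genes in TGQ are less clear. Against the somatic markers their mean log2 change differed by -0.08 (95% interval over samples -0.21 to 0.05, permutation over genes p = 0.53). All 12 genes stayed called higher after quantile normalization and with the authors' scaling. Their mean log2 change was then 0.765 and 0.427, against 0.558 in the main fit, so the authors' scaling, which lowers TGQ, did not remove the rise. Quantile normalization moved changes upward, with the median of the tested genes going from -0.22 to -0.1. Its result therefore says nothing against a scaling difference. By the marker comparison, a scaling difference of another size and a larger share of somatic RNA in TGQ cannot be told apart from a specific rise. What keeps this open is that the level of unchanged genes is not analysed here, and the markers were themselves selected for change. A mild induction of the response may add to it.

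Lower oocyte, sperm, vitellogenin and adult collagen mRNAs in TGQ formed a broad shift. A smaller germ line in animals otherwise at the same stage would leave the intestinal vitellogenins level with the other somatic markers, but they were lower by 3.09 on the log2 scale (difference of -3.09, 95% interval over samples -4.12 to -2.06). The 6 vitellogenin genes move together (estimated correlation 0.99), so the permutation over genes (p = 1.5e-06) overstates the evidence. Fewer germ cells of every stage alike would lower mitotic and meiotic genes as far as oocyte and sperm genes, but their mean was -0.35 against -1.46 (difference 1.11, 95% interval over samples 0.93 to 1.29). Of these 13 genes 7 were called lower and 1 higher, with a median of -0.34 against -0.22 for all tested genes, a camera adjusted p = 0.098 and a fry adjusted p = 0.059. These sets, too, hold only genes that had changed. Fewer germ cells of some stages cannot be told apart from the group. The X chromosome is little expressed in germ cells of many, but not all, stages. Outside the fixed lists, 74.6% of X-linked genes were higher against 40.1% of autosomal genes, a share already seen when this explanation was raised. An earlier point of L4 stays open for the same reason: 95% of listed moulting factors were higher in TGQ against 46.3% of other genes, but that list result had raised the explanation and is no test of it. A developmental delay caused by the TGQ condition and a difference in collection time were not separated by these samples.

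The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 4998 genes and 1090 with at least 2-fold change, each reached in 1 of the 10 splits; limma called at most 0 in the others, where at most 33 genes had an unadjusted p under 0.05. The table holds genes the authors had selected for a difference in the real split, so these gene counts were bound to favour it and test nothing. For lists, the real split called 20 and the highest other 23, and 3 of the 10 splits called at least as many as the real one. The other splits called 14 to 23 lists. Each of them sets 2 samples of one group and 1 of the other against the rest, so part of the group change stays in it, and what gave these list calls was not tested.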
